A study of Caenorhabditis elegans with 18 samples.

How the data were processed

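RNA was measured in whole Caenorhabditis elegans of the strain rrf-3(pk1436), which is hypersensitive to RNA interference, fed bacteria with an empty vector. The allele is given as in the labels, while the series' title names it pk1426, and the sources used here do not settle which is right. Per the labels, the 18 libraries fall into 6 ages (day 3, 6, 9, 12, 15 and 18), each with 3 replicates numbered 1, 3 and 4. The series' design text stops its list of ages at day 15, while 3 libraries carry the label day 18; the labels were followed, and what day 18 means rests on them. The worms grew in liquid culture at 20 °C, and the growth protocol describes how young larvae were removed by sedimentation, and dead worms, worms with hatched young inside and clumps of eggs by Percoll. Per the labels' protocols, rRNA was depleted from 500 ng of total RNA, stranded libraries were made with 11 cycles of PCR, and per the series' design text single reads of 51 bases were sequenced. No source used here says whether the 3 replicates of an age were separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels do not say from which event the days are counted. Knockdown of bec-1, pha-4, lgg-1 and atg-7 is named in the treatment protocol, and no knockdown library was analysed here.

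The values analysed are the raw read counts per gene that the authors deposited, 1 file per library, with no normalization. Each file holds 46748 WormBase gene identifiers. The submitters' processing notes name STAR 2.5.1b, featureCounts 1.4.6-p2, Subread and DESeq2 1.12.3, and the build WBcel235, with no role or order. The settings for strand and for reads that map to several places are not given in the sources used here. Reads of near-identical copies (histones, vitellogenins and other gene families) and of overlapping or antisense genes may therefore be split or mixed between genes, and values of such genes are uncertain. Names and coordinates come from the Ensembl annotation of WBcel235, release 115, in which 46449 of the identifiers were found; the other 299 took at most 0.27% of the counts of a library. No GC content was computed.

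Library totals ran from 17095196 to 27284109 counts, with a median of 22354056. Nuclear rRNA genes took 5.93% to 23.95% of the counts of a library and stayed in the totals. The deposited counts were checked for duplicated libraries: for every pair of replicates the median difference between counts exceeded sampling noise, with an index (1 would be sampling noise alone) from 1.49 to 4.77.

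Genes with low counts were left out with edgeR's filterByExpr, which kept 14998 genes. Counts were scaled with TMM factors, and all 18 libraries entered a single model with a mean for each age (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3). Differences between ages were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene counts as changed when its adjusted p is under 0.05. The comparisons were all 6 ages together, a linear trend per day, the 5 steps from each age to the next, day 18 against day 3, and day 18 against day 9. Levels are CPM (counts scaled to library size), computed from the deposited counts with the TMM-scaled totals, given as mean ± SD with n = 3, and fold changes are the model's log2 differences with their standard errors (SE).

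Before the data were examined, 53 gene lists were fixed, of which 52 had at least 5 measured members. Each list was compared with the other genes by camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 52 lists, and again with a correlation estimated for each list. The genes to be named were fixed by rule at the same time: rrf-3 and the 4 knockdown targets, for day 18 against day 3 the 10 rising and 10 falling genes with the largest fold change, for the other pairs of ages 5 and 5, and for a described list the 4 members with the smallest p. Genes of the fold-change part needed a mean of at least 5 CPM, an adjusted p under 0.05 and no overlap between the 3 libraries of each age, which chance gives in 10% of genes. Those with only a sequence name are left out, with their number given.

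The steps were tested on simulated data with known answers. Among 14666 simulated genes, 40 of the 67 genes changed 1.5-fold, 40 of the 67 changed 2-fold and 61 of the 66 changed 4-fold were found between day 18 and day 15, and 7 of the 148 calls were false. Between day 18 and day 3, 33 of the 67 genes changed 1.5-fold were found, and 5 of 138 calls were false. For the 6 ages together 10 of 141 calls were false. Only 200 genes were changed, in both directions, and each gene was drawn independently. The simulation therefore tests neither the scaling when most genes change nor the list test when genes are correlated. Alternatives tried were RLE scaling, library totals without scaling factors, no filter, a stricter filter (at least 5 CPM in at least 3 libraries), DESeq2 1.42.0, the replicate number as a block, protein-coding genes only, a limit of 2-fold, only the 6 libraries compared, leaving out each library in turn and, for the lists, the test fry. An alternative chosen after seeing the data leaves out the 3 libraries that stood farthest from their age, which leaves 1 library at day 9. Figures were drawn with matplotlib 3.10.9.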

Results

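The series follows RNA levels in whole rrf-3(pk1436) worms from day 3 to day 18, and asks how they change with age. There were 3 libraries for each of the 6 ages. Total counts per library ran from 17095196 (day 9 replicate 3) to 27284109 (day 12 replicate 1), and 12520 to 14842 genes had at least 10 counts in a library. Nuclear rRNA took 5.93% to 23.95% of the counts, with the highest shares in day 9 replicate 3 (23.95%), day 15 replicate 1 (15.79%) and day 12 replicate 4 (12.97%). Day 9 replicates 1 and 3 and day 15 replicate 1 stood farther from the mean of their age than other libraries, with an SD of deviations over genes of 0.269, 0.198 and 0.172 (log2), against 0.056 to 0.165 in the other 15.

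The gene rrf-3 (WBGene00004510, II:8162465-8168651 in WBcel235), which encodes an RNA-directed RNA polymerase and carries the strain's mutation, was counted in all 18 libraries. Its level was 63.9 ± 2.37 CPM at day 3, 56.97 ± 1.02 at day 6 and 64.01 ± 0.529 at day 18 (SD, n = 3). Counts over a whole gene do not show which part of it a mutant lacks, so they do not check the genotype. Between day 18 and day 3 the log2 difference was 0.004 (SE 0.053, adjusted p = 0.958). Among the 4 genes the protocol names as knockdown targets, the autophagy genes bec-1 and atg-7 rose from day 3 to day 18, from 85.9 ± 4.65 to 101 ± 1.60 CPM (adjusted p = 0.00125) and from 95.3 ± 7.68 to 116.2 ± 4.66 CPM (adjusted p = 0.00112). The level of lgg-1, another autophagy gene, was 336 ± 13.1 CPM at day 3 and 358.5 ± 20.6 at day 18 (adjusted p = 0.197). It passed with the stricter filter (adjusted p = 0.0482) and without the 3 libraries that stand apart (adjusted p = 0.0201). The FOXA transcription factor gene pha-4 rose from 8.93 ± 1.81 to 26.1 ± 15.1 CPM (log2 difference 1.54, SE 0.349, adjusted p = 0.00106).

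Across the 6 ages, 11153 of 14998 genes (74.4%) changed. Day 3 held the highest mean of 4154 genes and the lowest mean of 4096, day 18 the highest of 2218 and the lowest of 3271. The first principal component, with 55.3% of the variance, placed day 3 far from all later ages, and the second, with 18.3%, had day 3 and day 18 on the side opposite to day 6. From day 3 to day 6, 3818 genes rose and 3335 fell, the largest number for a step between neighbouring ages. Each of the later steps changed 851 to 1803 genes.

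**Figure D1:**
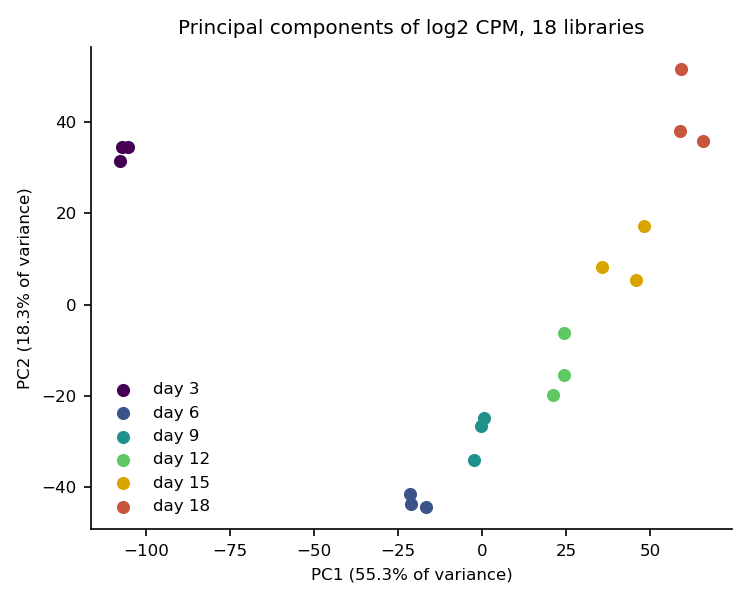
Principal components of log2 CPM in the 18 libraries, 1 point per library, coloured by age. The 3 libraries of day 3 lie between -107.7 and -105.3 on the first component, and the 3 of day 18 between 58.7 and 65.6.

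**Figure D2:**
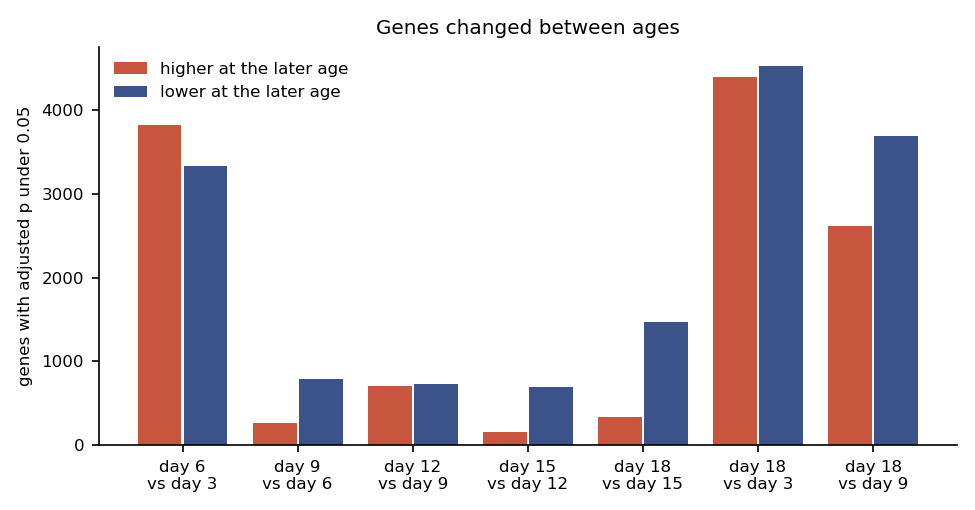
Number of genes with an adjusted p under 0.05 in each comparison of ages, split into genes higher (red) and lower (blue) at the later age. The step from day 6 to day 9 has 257 and 789, the step from day 15 to day 18 has 332 and 1471.

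Day 18 against day 3 asks what differs between the oldest and the youngest worms of the series. Yolk protein genes and most genes of lysosomal enzymes, lysozymes and infection responses fell, while most genes of ribosomes, cilia and synapses rose. Of these lists, only lysosomal hydrolases and infection response genes kept their call with an estimated correlation. All 6 vitellogenins, which encode yolk proteins made in the intestine, fell. The level of vit-6 (WBGene00006930, IV:8261157-8266459) went from 20530 ± 1128 to 571 ± 129.7 CPM, a 36.0-fold drop (log2 -5.17, SE 0.265, adjusted p = 2.87e-11). Of 47 lysosomal hydrolases, which break down proteins, lipids and sugars in lysosomes, 41 fell and 2 rose (41 and 2 adjusted over the list alone), with a median log2 change of -2.23. Of 14 genes of intestinal structure and transport, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 0.000145, adjusted p = 0.161 with an estimated correlation). Among these, the esterase gene ges-1 went from 62.75 ± 3.20 to 2.72 ± 0.999 CPM. In all, 4399 genes rose and 4527 fell.

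Among the lysosomal hydrolases, the cathepsin B-like protease gene cpr-6 (WBGene00000786) fell from 710.3 ± 23.8 to 25 ± 5.62 CPM, the cathepsin D-like asp-4 (WBGene00000217) from 704 ± 41.5 to 69.1 ± 8.61 and gba-4 (WBGene00021160), related to glucocerebrosidase, from 27.3 ± 2.05 to 0.379 ± 0.18 (n = 3). The list differed from other genes by camera (adjusted p = 2.66e-32), also with adjusted p = 0.0431 with an estimated correlation. Infection response genes fell with them: 13 of 15 were lower and 1 higher (14 and 1 adjusted over the list alone), with a median of -4.70, a camera adjusted p = 2.65e-13 and an adjusted p = 0.0431 with an estimated correlation. Of these, irg-7 (WBGene00018237, X:3235754-3243636) fell from 1030 ± 37.1 to 39.7 ± 5.10 CPM and irg-8 (WBGene00022645) from 676 ± 49.6 to 7.20 ± 1.13. The vitellogenins' camera adjusted p was 5.06e-07, and adjusted p = 0.163 with an estimated correlation. Near-identical sequence makes the values of vit-3, vit-4 and vit-5 uncertain.

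Antimicrobial peptides and lysozymes fell in 39 of 57 members and rose in 9 (39 and 11 adjusted over the list alone). The lysozyme gene lys-2 (WBGene00003091, V:10280307-10281474) went from 289.7 ± 25.3 to 0.802 ± 0.324 CPM, and the saposin-like spp-5 (WBGene00004990) from 429 ± 26.6 to 13.6 ± 2.38. Of 97 C-type lectins, a family of sugar-binding proteins, 67 fell and 14 rose (68 and 14 adjusted over the list alone), among them clec-65 (115.6 ± 1.27 to 3.56 ± 0.683 CPM) and clec-1 (178 ± 11.4 to 6.24 ± 1.44). The camera adjusted p values were 3.83e-11 and 9.35e-14. For the antimicrobial list the adjusted p = 0.274 with an estimated correlation, and for the lectins adjusted p = 0.063 with an estimated correlation. Members of the lectin family are alike in sequence, which leaves single values uncertain.

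Fat metabolism genes were lower at day 18. Of 20 genes of fatty acid synthesis and desaturation, 14 fell and 0 rose (14 and 0 adjusted over the list alone). The stearoyl-CoA desaturase gene fat-7 fell from 39.2 ± 3.93 to 0.326 ± 0.15 CPM, fat-5, another desaturase, from 179 ± 10.4 to 13.8 ± 3.05, and the delta-12 desaturase fat-2 from 625 ± 29.5 to 65.9 ± 8.46. For 41 genes of fatty acid beta-oxidation the count was 32 lower and 2 higher (33 and 2 adjusted over the list alone). The acyl-CoA oxidase gene acox-1.5 fell from 55.3 ± 4.66 to 1.68 ± 0.373 CPM and the dehydrogenase gene acdh-10 from 107.9 ± 4.84 to 50.9 ± 0.797. With library totals 21 beta-oxidation genes were lower. By camera the adjusted p = 2.37e-07 and, for beta-oxidation, 7.44e-08, against adjusted p = 0.137 with an estimated correlation and, for beta-oxidation, adjusted p = 0.115 with an estimated correlation.

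Structural genes of muscle and cuticle fell too. The muscle list had 26 lower and 3 higher of 36 (26 and 3 adjusted over the list alone). The troponin I gene unc-27 (WBGene00006764) went from 131 ± 14.2 to 13.5 ± 0.725 CPM, troponin C gene pat-10 from 194 ± 16.4 to 38.8 ± 3.02 and the myosin light chain gene mlc-2 from 123.1 ± 5.21 to 27.2 ± 2.35. Of 111 cuticle collagens, 61 fell and 14 rose (61 and 14 adjusted over the list alone), with col-181 at 529 ± 46.5 and then 15.8 ± 1.43 CPM. Histones were lower in 28 of 34 members and higher in 3 (28 and 4 adjusted over the list alone). Of these, his-38 fell from 73.5 ± 5.58 to 8.06 ± 0.482 CPM and his-60 from 839.7 ± 74.3 to 199.9 ± 15.7, values that near-identical copies make uncertain. Of 12 oxidative phosphorylation genes encoded by mitochondrial DNA, 11 fell and 0 rose (11 and 0 adjusted over the list alone), the cytochrome b gene CYTB from 1035 ± 84.8 to 328.6 ± 26.3 CPM and COX2 from 545 ± 37.2 to 118 ± 8.77. Mitochondrial rRNA did not fall with them, at 2.34 ± 0.22% of the counts at day 3 and 2.93 ± 0.10% at day 18. The median level of nuclear-encoded oxidative phosphorylation genes (log2 CPM centred on each gene's mean) was 0.09 to 0.138 at day 3 and 0.03 to 0.081 at day 18. Tested by camera, the adjusted p values were 1.11e-07 for muscle, 0.000888 for collagens, 4.26e-10 for histones and 0.00672 for the mitochondrial genes. Of the alternatives run on these lists, only the estimated correlation ended the calls, and in that order it gave adjusted p = 0.285 with an estimated correlation, adjusted p = 0.594 with an estimated correlation, adjusted p = 0.163 with an estimated correlation and adjusted p = 0.583 with an estimated correlation.

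On the rising side, 75 of 80 cytosolic ribosomal protein genes were higher and 1 lower (75 and 1 adjusted over the list alone), by a small median of 0.40. Of these, rpl-10 rose from 1255 ± 6.59 to 1832 ± 101.6 CPM and rpl-24.2 from 53.6 ± 2.59 to 100.3 ± 7.99. Of 35 ciliary and intraflagellar transport genes, active in ciliated sensory neurons, 30 rose and 0 fell (32 and 0 adjusted over the list alone), among them the dynein gene che-3 (7.69 ± 1.33 to 15.6 ± 2.49 CPM) and ift-43 (7.38 ± 0.553 to 14.9 ± 0.891). Synaptic genes rose in 20 of 34 cases and fell in 4 (21 and 4 adjusted over the list alone). The level of unc-13 (WBGene00006752), needed to prime synaptic vesicles, went from 18.3 ± 0.174 to 58.7 ± 5.16 CPM and the active zone gene cla-1 from 24.7 ± 1.52 to 154 ± 4.16. Chemoreceptor genes were higher in 57 of 109 cases and lower in 13 (57 and 13 adjusted over the list alone), with srr-4 rising from 19.1 ± 0.93 to 82.5 ± 11.4 CPM and str-7 falling from 3.89 ± 0.341 to 0.144 ± 0.0352. The camera adjusted p values were 2.07e-09 for ribosomal proteins, 4.86e-05 for cilia, 0.00563 for synapses and 0.000898 for chemoreceptors. For the 4 lists in turn, the alternative gave adjusted p = 0.399 with an estimated correlation, adjusted p = 0.163 with an estimated correlation, adjusted p = 0.285 with an estimated correlation and adjusted p = 0.285 with an estimated correlation. With the stricter filter the call of the ciliary list ended (adjusted p = 0.0501).

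The pals family, whose members respond to intracellular infection, split: 25 of 32 rose and 4 fell (25 and 4 adjusted over the list alone), with pals-27 up from 1.41 ± 0.28 to 9.40 ± 1.36 CPM and pals-23 down from 19.1 ± 1.14 to 2.44 ± 0.119 (camera adjusted p = 0.000883, adjusted p = 0.285 with an estimated correlation, and 0.0715 with the stricter filter). Early embryonic zygotic genes were lower in 22 of 29 cases and higher in 5 (22 and 5 adjusted over the list alone). The level of vet-6 fell from 9.86 ± 0.952 to 1.80 ± 0.514 CPM, while sdz-35 rose from 1.44 ± 0.35 to 16.9 ± 1.63 (camera adjusted p = 0.0231, adjusted p = 0.285 with an estimated correlation, and 0.489 with the stricter filter). For autophagy, the subject of the knockdown targets, the 34 genes went both ways: 12 rose and 8 fell (11 and 8 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.623). Without day 18 replicate 1, 6 rose and 6 fell. The receptor gene sqst-1 (WBGene00011737, IV:12034282-12036891), whose protein carries cargo to autophagosomes, rose from 188.5 ± 0.37 to 441 ± 33.6 CPM and allo-1, another receptor gene, from 271 ± 6.97 to 435 ± 24.1. In contrast, sepa-1 fell from 14.6 ± 1.20 to 2.60 ± 0.218 CPM and atg-2 from 184.9 ± 3.60 to 112.7 ± 10.3.

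By fold change, the rising genes with a symbol were cpr-2 (WBGene00000782, V:16532936-16534100), a cathepsin B-like protease gene (0.106 ± 0.0621 to 10.7 ± 4.16 CPM, log2 6.62, SE 0.462), droe-8 (log2 4.96, SE 0.229) and chtb-1 (log2 4.53, SE 0.221). The falling ones were sysm-1 (194 ± 6.32 to 0.291 ± 0.334 CPM, log2 -9.48, SE 0.514), vit-4 (log2 -9.10), vit-3 (log2 -8.65), ctsa-1.2 (log2 -8.58) and lys-2 (log2 -8.53). Another 7 rising and 5 falling genes of the rule have only a sequence name. Their adjusted p ran from 1.75e-13 for lys-2 to 1.57e-09 for cpr-2. With library totals in place of TMM factors the median of all genes moved from 0.016 to 0.178 and 62.9% of the changed genes were higher, against 49.3%. None of the lists described here changed the sign of its median.

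**Figure D3:**
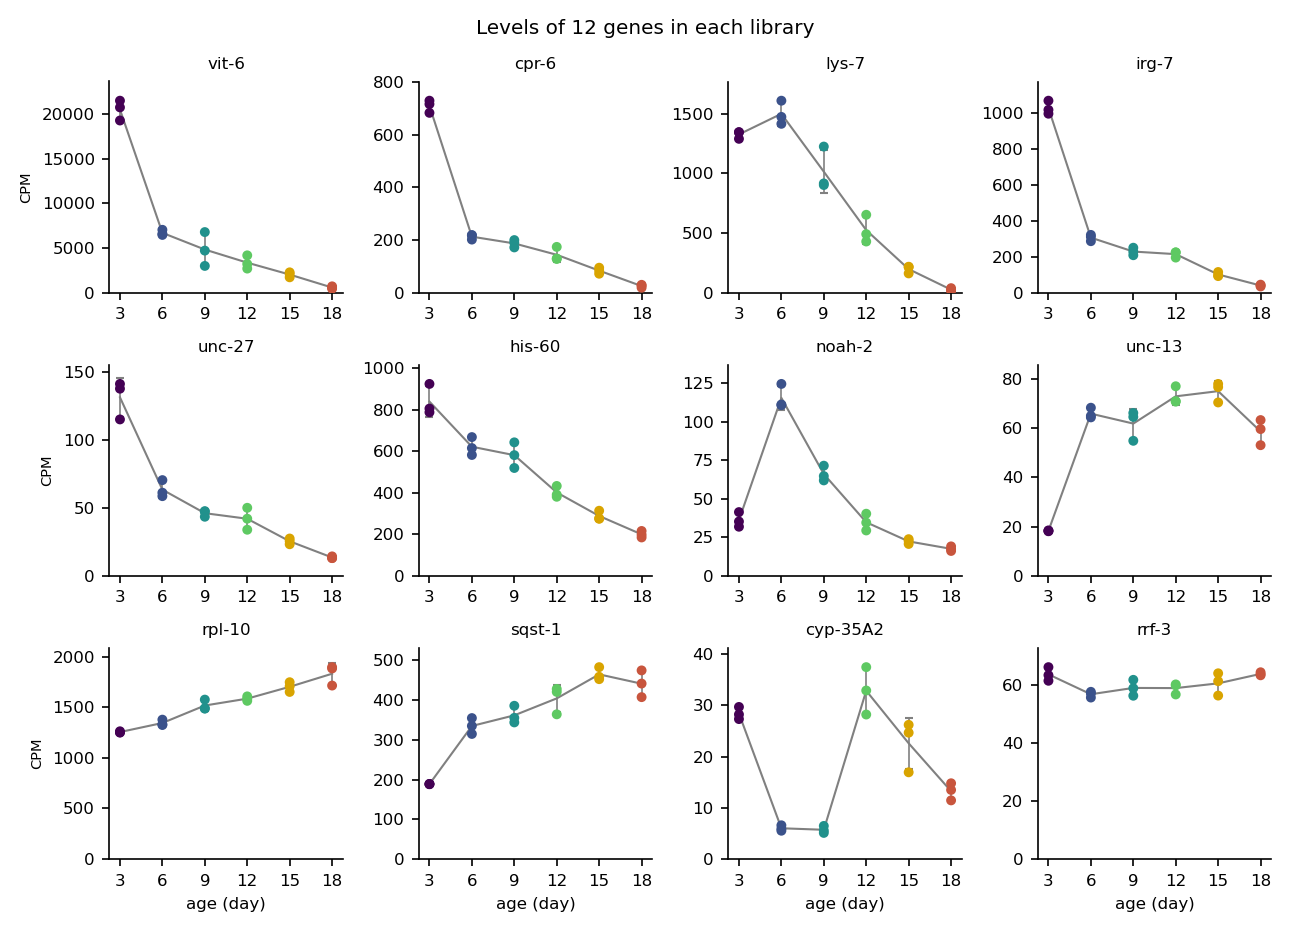
CPM of 12 genes in each of the 18 libraries by age, with the line through the means and bars of 1 SD (n = 3); each axis starts at 0. The mean of vit-6 falls at every age from 20530 at day 3, while single libraries of day 6 and day 9 overlap. Day 9 replicate 3 (6791) lies above day 6 replicates 3 (6597) and 4 (6470). The level of unc-13 stays above its day 3 level at all later ages.

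The step from day 3 to day 6 asks what changes first. Most genes of cilia, synapses and moulting rose, and most genes of the intestine, of lysosomes and of infection responses fell. With an estimated correlation the calls of cilia, intestine and infection responses held. Those of synapses, moulting and lysosomes were lost. Cuticle collagens went both ways, with 38 of 111 higher and 31 lower (39 and 32 adjusted over the list alone, camera adjusted p = 0.767). Of 35 ciliary genes, 33 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 change of 1.67. Of these, che-3 went from 7.69 ± 1.33 to 19.5 ± 0.872 CPM and the kinase gene dyf-5 from 0.644 ± 0.157 to 3.86 ± 0.756. Moulting and cuticle assembly genes rose in 40 of 62 cases and fell in 6 (41 and 7 adjusted over the list alone). The level of ptr-4 (WBGene00004219, X:6060758-6065986), a patched-related gene, went from 5.19 ± 1.29 to 47.6 ± 0.822 CPM, ptr-10 from 1.15 ± 0.0353 to 13.9 ± 1.26 and noah-2 (WBGene00009926), which encodes a protein of the embryonic and larval outer covering, from 36.2 ± 4.82 to 115.6 ± 7.81. In total 3818 genes rose and 3335 fell.

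By camera the adjusted p values were 6.13e-12 for cilia and 7.3e-09 for moulting. The ciliary call held with adjusted p = 0.0437 with an estimated correlation, and the moulting call was lost with adjusted p = 0.152 with an estimated correlation. Of 22 markers of mid and late embryos, 11 rose and 1 fell at this step, with a median log2 change of 0.77, and the others did not pass. Synaptic genes rose in 23 of 34 cases and fell in 1 (23 and 1 adjusted over the list alone). Here unc-13 went from 18.3 ± 0.174 to 65.9 ± 2.11 CPM (camera adjusted p = 3.63e-06, adjusted p = 0.152 with an estimated correlation). The pals family rose in 22 of 32 cases and fell in 4 (23 and 5 adjusted over the list alone). Of these, pals-14 went from 2.67 ± 0.234 to 10.6 ± 2.28 CPM (camera adjusted p = 0.00647, adjusted p = 0.584 with an estimated correlation, and 0.0782 with the stricter filter).

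Infection response genes fell in 10 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone). The level of irg-8 went from 676 ± 49.6 to 38.8 ± 3.14 CPM and irg-7 from 1030 ± 37.1 to 307 ± 18.0 (camera adjusted p = 3.62e-10, adjusted p = 0.0437 with an estimated correlation). Of 14 genes of intestinal structure and transport, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with act-5, the actin of intestinal microvilli, from 204.9 ± 2.78 to 56.99 ± 4.17 CPM and the intermediate filament gene ifd-2 from 20.0 ± 2.88 to 6.84 ± 0.638 (camera adjusted p = 2.01e-07, adjusted p = 0.0437 with an estimated correlation). Lysosomal hydrolases were lower in 34 of 47 cases and higher in 7 (35 and 7 adjusted over the list alone), among them gba-4 (27.3 ± 2.05 to 3.38 ± 0.216 CPM) and cpr-3 (143 ± 10.4 to 54.2 ± 2.32). Camera gave this list adjusted p = 3.62e-10, and adjusted p = 0.37 with an estimated correlation. All 6 vitellogenins fell, vit-6 from 20530 ± 1128 to 6704 ± 301 CPM (camera adjusted p = 0.000369, adjusted p = 0.468 with an estimated correlation). Muscle genes fell in 20 of 36 cases and rose in 2 (21 and 3 adjusted over the list alone). In this list, unc-27 went from 131 ± 14.2 to 63.4 ± 6.21 CPM and the myosin gene myo-3 from 113.5 ± 7.68 to 70.5 ± 5.29 (camera adjusted p = 0.00122, adjusted p = 0.666 with an estimated correlation).

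By fold change, the rising genes with a symbol were cpr-2 (0.106 ± 0.0621 to 7.36 ± 1.03 CPM, log2 6.09), the acyl-CoA synthetase gene acs-24 (log2 4.72) and bus-8B (log2 4.20). The falling ones were the folate transporter gene folt-2 (33.2 ± 6.33 to 0.964 ± 0.268 CPM, log2 -5.08), col-160 (log2 -4.63), the acyl-CoA dehydrogenase gene acdh-1 (196 ± 19.7 to 8.19 ± 0.529 CPM, log2 -4.58), vit-3 (log2 -4.52) and vit-4 (log2 -4.24). Another 2 rising genes have only a sequence name. Proteasome genes were lower in 29 of 31 cases (29 adjusted over the list alone; pbs-5 from 187.5 ± 3.94 to 155 ± 2.15 CPM). Oocyte genes were lower in 22 of 31 (24 adjusted over the list alone; the yolk receptor gene rme-2 from 1757 ± 51.6 to 1336 ± 20.4 CPM). Each list had 0 higher genes. These small changes depended on the scaling. With library totals 0 proteasome and 2 oocyte genes passed. The median of all genes was 0.171 in place of -0.005, and 78.4% of the changed genes were higher, against 53.4%. Camera adjusted p was 0.000349 for the proteasome and 0.000198 for the oocyte list, with adjusted p = 0.0577 with library totals and adjusted p = 0.533 with an estimated correlation for the first and adjusted p = 0.666 with an estimated correlation for the second.

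**Figure D4:**
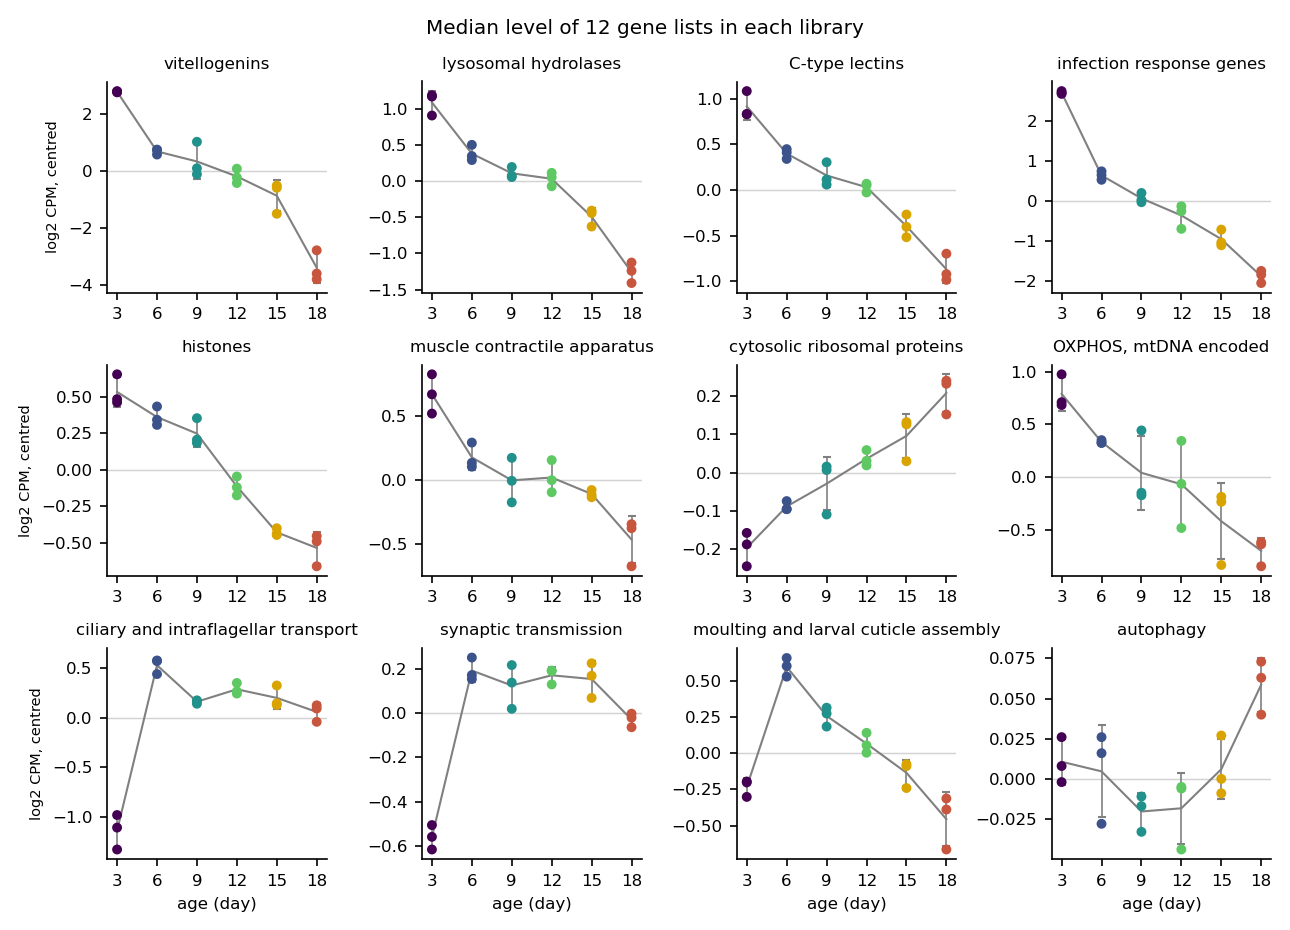
Median over the members of 12 gene lists of log2 CPM centred on each gene's mean, in each of the 18 libraries by age, with the line through the means and bars of 1 SD (n = 3). The ciliary, synaptic and moulting lists are higher at day 6 than at day 3, and the lysosomal list is lowest at day 18; the vertical scales differ between panels.

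The step from day 6 to day 9 asks how the early changes go on. Part of the cuticle collagens, moulting genes and basement membrane genes fell, and these list calls were lost with an estimated correlation. With the preset correlation 10 lists were called higher and 13 lower than other genes, of which only part is described. Of 111 collagens 37 were lower and 0 higher (52 and 1 adjusted over the list alone). Among them, dpy-17 went from 66.6 ± 1.63 to 27.04 ± 2.71 CPM and dpy-7 from 8.57 ± 0.391 to 3.15 ± 0.592. Of 62 moulting genes 16 fell and 0 rose (27 and 1 adjusted over the list alone). Here noah-2 went from 115.6 ± 7.81 to 66.1 ± 4.91 CPM, and noah-1, from 157 ± 13.3 to 85.8 ± 10.4. The agrin gene agr-1 (21.4 ± 0.738 to 9.68 ± 0.986 CPM) and the laminin gene lam-3 (77.8 ± 4.38 to 55.8 ± 6.42) were among 5 of 16 basement membrane genes that fell, with 0 higher (9 and 0 adjusted over the list alone). The collagens' list level (median log2 CPM centred on each gene's mean) was -1.21 in day 9 replicate 1, which stands apart, and -0.04 and 0.13 in replicates 3 and 4, against 1.08, 0.75 and 0.41 at day 6. Without day 9 replicate 1, 32 of 117 collagens were lower, and without day 6 replicate 1, 20. Without the 3 libraries that stand apart, which leaves 1 library at day 9, 14 of 133 collagens were lower. Of the basement membrane genes 3 were lower without day 6 replicate 1. Of the 22 markers of mid and late embryos, 9 fell and 0 rose at this step (median -0.35). In total 257 genes rose and 789 fell.

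Camera gave adjusted p values of 7.44e-19 for collagens, 8.04e-10 for moulting and 1.49e-06 for the basement membrane, all lost at adjusted p = 0.188 with an estimated correlation or, for moulting, adjusted p = 0.186 with an estimated correlation. The pals family fell in 11 of 32 cases and rose in 0 (18 and 0 adjusted over the list alone; pals-14 from 10.6 ± 2.28 to 4.48 ± 0.517 CPM), and infection response genes in 7 of 15 with 0 higher (9 and 1 adjusted over the list alone; irg-8 from 38.8 ± 3.14 to 15.4 ± 3.30 CPM). Without day 6 replicate 1, 6 pals and 3 infection response genes were lower. Infection response genes were lower in 4 cases without day 6 replicate 4 or day 9 replicate 4. Without the 3 libraries that stand apart, with 1 library left at day 9, 3 pals genes were lower, and the calls of col-42 (adjusted p = 0.0775) and pqn-75 (0.139) ended. Their camera adjusted p values were 4.77e-06 and 7.27e-05, and for each adjusted p = 0.188 with an estimated correlation. By fold change, cpr-2 rose to 31.2 ± 2.34 CPM (log2 2.07) and the aquaporin gene aqp-1 from 9.62 ± 0.759 to 22.9 ± 2.86, and the collagen genes col-42 (log2 -2.29), sqt-3 (log2 -2.16) and col-103 (log2 -2.11) and pqn-75 (log2 -2.06) fell. Another 3 rising and 1 falling genes have only a sequence name. Leaving out a single library ended the call of pqn-75 (adjusted p = 0.165 without day 6 replicate 1, 0.0621 without day 6 replicate 3, 0.0655 without day 9 replicate 1 and 0.0546 without day 9 replicate 4), of col-103 (0.0542 without day 6 replicate 1) and of aqp-1 (0.0611 without day 6 replicate 3). Fitted to only the 6 libraries compared, the calls of col-42 (adjusted p = 0.0888), sqt-3 (0.117), col-103 (0.148), pqn-75 (0.14) and lam-3 (0.0524) ended. The count of changed genes was 477 without day 6 replicate 1, 565 without day 6 replicate 3 and 668 without day 6 replicate 4. With library totals 9.6% of the changed genes were higher, against 24.6%.

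From day 9 to day 12, part of the UDP-glucuronosyltransferase and cytochrome P450 genes rose and part of the histone genes fell. All of these list calls were lost with an estimated correlation. Glutathione S-transferases, another family that acts on foreign compounds, did not pass as a list (3 of 42 higher and 1 lower, camera adjusted p = 0.0698). Of 61 UDP-glucuronosyltransferases, enzymes that attach sugar to foreign compounds, 18 rose and 0 fell (22 and 1 adjusted over the list alone). Of these, ugt-22 went from 7.51 ± 0.652 to 19.5 ± 1.67 CPM and ugt-46 (WBGene00015141) from 5.14 ± 0.381 to 12.8 ± 2.31. Cytochrome P450 genes rose in 16 of 68 cases and fell in 4 (21 and 5 adjusted over the list alone). In this list, cyp-35A2 (WBGene00015400, V:7362319-7364182) went from 5.72 ± 0.691 to 32.9 ± 4.63 CPM, and cyp-35C1, from 6.09 ± 0.515 to 27.3 ± 5.77. Histones fell in 20 of 34 cases and rose in 0 (23 and 0 adjusted over the list alone). Among them, his-38 went from 32.7 ± 3.58 to 18.65 ± 1.115 CPM and his-2 from 110.6 ± 3.45 to 75.7 ± 5.61. Fatty acid synthesis genes fell in 9 of 20 cases and rose in 1 (11 and 3 adjusted over the list alone). Here the synthase gene fasn-1 went from 1269 ± 128.7 to 913 ± 85.1 CPM, and the desaturase gene fat-6, from 162 ± 10.6 to 100.1 ± 17.5.

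With library totals the balance of the fatty acid synthesis genes turned, with 2 lower and 3 higher, and 11 histones were lower. Of the fatty acid synthesis genes 5 were lower without day 12 replicate 3 or without day 12 replicate 4. Of the day 9 libraries, replicates 1 and 3 stand apart. Without them and day 15 replicate 1, which leaves 1 library at day 9, 6 of 38 histones and 4 fatty acid synthesis genes were lower and 10 P450 genes higher. In this step 700 genes rose and 732 fell. Camera gave adjusted p values of 6.48e-08 for the glucuronosyltransferases, 0.000108 for the P450 genes, 3.02e-18 for histones and 0.00105 for fatty acid synthesis. In the same order the alternative gave adjusted p = 0.456 with an estimated correlation, adjusted p = 0.499 with an estimated correlation, adjusted p = 0.209 with an estimated correlation and adjusted p = 0.449 with an estimated correlation. By fold change, pgph-3 (2.55 ± 0.181 to 15.9 ± 0.521 CPM, log2 2.65) rose beside both P450 genes, and ilys-5, a lysozyme gene, fell from 23.7 ± 4.01 to 6.16 ± 2.18 CPM (log2 -1.92). Another 2 rising and 4 falling genes have only a sequence name. The treatment protocol describes a move to plates on day 9 and a harvest at day 12 for the knockdown experiment, and the labels do not say whether the day 12 libraries used here went through that move, so the step and such a move cannot be told apart. Fitted to only the 6 libraries compared, the call of fasn-1 ended (adjusted p = 0.0549). The count of changed genes was 842 without day 9 replicate 1, 787 without day 12 replicate 3 and 877 without day 12 replicate 4. With library totals 72.2% of the changed genes were higher, against 48.9%.

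The step from day 12 to day 15 brought a further fall of part of the lysosomal genes, a list call that was lost with an estimated correlation. With the preset correlation 12 lists were called higher and 17 lower than other genes, and only part of them is described. Of 47 lysosomal hydrolases 24 fell and 0 rose (37 and 0 adjusted over the list alone), with a median log2 change of -0.62. The aspartyl protease gene asp-3 went from 180 ± 23.2 to 74.6 ± 16.9 CPM and the acid ceramidase gene asah-1 (WBGene00010769) from 28.5 ± 4.17 to 15.0 ± 0.606. C-type lectins fell in 17 of 97 cases and rose in 2 (28 and 2 adjusted over the list alone). Of these, clec-1 went from 50.2 ± 3.30 to 19.7 ± 3.42 CPM. Histones fell in 16 of 34 cases and rose in 0 (21 and 0 adjusted over the list alone). In this list, his-60 went from 402 ± 27.7 to 288.6 ± 21.9 CPM. Beta-oxidation genes fell in 9 of 41 cases and rose in 0 (14 and 0 adjusted over the list alone; the dehydrogenase gene hacd-1 from 17.1 ± 6.02 to 6.08 ± 2.62 CPM), and pals genes rose in 9 of 32 cases and fell in 1 (11 and 1 adjusted over the list alone; pals-39 from 4.20 ± 0.949 to 8.10 ± 0.806 CPM).

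With library totals 8 histones and 5 beta-oxidation genes were lower. Without day 12 replicate 1, 15 lysosomal, 11 lectin, 6 histone and 4 beta-oxidation genes were lower and 4 pals genes higher. Without day 15 replicate 1, 15 lysosomal, 10 histone and 4 beta-oxidation genes were lower and 4 pals genes higher. Of the beta-oxidation genes 5 were lower without day 12 replicate 4, without day 15 replicate 4 or without the 3 libraries that stand apart. Histones were lower in 8 cases without day 15 replicate 3, and 5 pals genes were higher without day 12 replicate 4 or without the 3 libraries that stand apart. Altogether 158 genes rose and 693 fell between these ages. Camera gave adjusted p values of 1.9e-28 for lysosomal hydrolases, 1.6e-10 for lectins, 6.21e-11 for histones, 2.02e-05 for beta-oxidation and 1.18e-06 for pals. In the same order the alternative gave adjusted p = 0.126 with an estimated correlation, adjusted p = 0.126 with an estimated correlation, adjusted p = 0.145 with an estimated correlation, adjusted p = 0.152 with an estimated correlation and adjusted p = 0.145 with an estimated correlation. By fold change, the F-box gene fbxa-24 rose from 13.1 ± 0.763 to 27.1 ± 0.395 CPM (log2 1.05), and drd-50 (log2 -2.02), clec-218 (4.64 ± 0.674 to 1.18 ± 0.296 CPM) and the thaumatin-like gene thn-2 (22.3 ± 7.45 to 6.02 ± 0.93 CPM, log2 -1.90) fell. Another 4 rising and 2 falling genes have only a sequence name. Fitted to only the 6 libraries compared, the call of hacd-1 ended (adjusted p = 0.0556). The count of changed genes was 394 without day 12 replicate 1, 387 without day 15 replicate 1 and 464 with library totals.

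From day 15 to day 18 yolk proteins, most lysosomal enzymes and part of the antimicrobial and lysozyme genes fell further. Camera with the preset correlation called 13 lists higher and 20 lower than other genes, and only part of them is described. With an estimated correlation only the calls of the lysosomal lists held. Of 47 lysosomal hydrolases 32 fell and 0 rose (33 and 0 adjusted over the list alone), with a median log2 change of -0.78. The level of cpr-6 went from 83.7 ± 11.4 to 25 ± 5.62 CPM and asah-1 from 15.0 ± 0.606 to 5.17 ± 0.328. Of 6 lysosomal lipases 4 fell and 0 rose (6 and 0 adjusted over the list alone). Among them, lipl-1 went from 7.87 ± 1.61 to 2.40 ± 0.0361 CPM. Both calls held by camera, with adjusted p values of 3.93e-34 and 2.19e-08 and, for each, adjusted p = 0.0356 with an estimated correlation. Antimicrobial peptides and lysozymes fell in 25 of 57 cases and rose in 0 (33 and 1 adjusted over the list alone). Here lys-7 (WBGene00003096, V:3481432-3482600) went from 197.5 ± 31.3 to 24.9 ± 11.3 CPM and spp-14 from 31.2 ± 4.08 to 11.1 ± 1.19. All 6 vitellogenins fell again, vit-6 from 2026 ± 283 to 571 ± 129.7 CPM and vit-5 from 393.7 ± 73.8 to 87.9 ± 26.6.

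Muscle genes fell in 11 of 36 cases and rose in 0 (16 and 0 adjusted over the list alone). Of these, unc-27 went from 25.4 ± 2.11 to 13.5 ± 0.725 CPM and myo-3 from 53.5 ± 2.13 to 35.3 ± 1.73. Cytochrome P450 genes fell in 23 of 68 cases and rose in 4 (29 and 4 adjusted over the list alone). In this list, cyp-13A5 went from 75.4 ± 4.86 to 37.8 ± 7.85 CPM. The lists' adjusted p values by camera were 1.27e-16 for the antimicrobial list, 3.13e-13 for vitellogenins, 1.42e-07 for muscle and 1.21e-06 for the P450 genes. In the same order the alternative gave adjusted p = 0.136 with an estimated correlation, adjusted p = 0.0597 with an estimated correlation, adjusted p = 0.216 with an estimated correlation and adjusted p = 0.216 with an estimated correlation. By fold change, ugt-46 rose from 20.6 ± 1.38 to 36.0 ± 2.12 CPM (log2 0.81), and lys-2 (8.49 ± 2.54 to 0.802 ± 0.324 CPM, log2 -3.42), folt-2 (log2 -3.41), vit-1 (log2 -3.23) and vit-4 (log2 -3.22) fell. Another 4 rising and 1 falling genes have only a sequence name. The call of folt-2 (adjusted p = 0.0305) ended without day 15 replicate 1 (adjusted p = 0.072), day 15 replicate 4 (0.0674), day 18 replicate 1 (0.0835) or day 18 replicate 4 (0.133). Without day 18 replicate 4, 14 antimicrobial and 14 P450 genes were lower, and without day 15 replicate 3, 14 P450 genes. Between these ages 332 genes rose and 1471 fell. The count was 863 without day 15 replicate 3, 784 without day 18 replicate 4 and 905 with library totals, where 3.8% of the changed genes were higher, against 18.4%.

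Day 18 against day 9 covers the later part of the time course, in which 2617 genes rose and 3694 fell. Lysosomal genes fell as a block: 41 of 47 hydrolases were lower and 0 higher (41 and 0 adjusted over the list alone). Among them, cpr-1 went from 65.2 ± 2.15 to 4.51 ± 0.69 CPM and asp-5 from 217.9 ± 22.4 to 27.4 ± 5.74, and all 6 lysosomal lipases fell, lipl-5 from 60.7 ± 4.42 to 5.32 ± 1.16. Their camera adjusted p values were 1.14e-33 and 9.21e-10, and for each adjusted p = 0.038 with an estimated correlation. Of 17 targets of DAF-16, the FOXO transcription factor, 12 fell and 1 rose (12 and 1 adjusted over the list alone). Here lys-7 went from 1015 ± 182.7 to 24.9 ± 11.3 CPM and the catalase gene ctl-2 from 48.9 ± 0.526 to 16.4 ± 3.42. Moulting genes fell in 41 of 62 cases and rose in 6 (43 and 6 adjusted over the list alone; ptr-4 from 27.3 ± 2.33 to 5.07 ± 0.592 CPM), and histones in 26 of 34 with 2 higher (27 and 2 adjusted over the list alone; his-61 from 401 ± 33.7 to 157 ± 8.07 CPM). The embryo markers fell as well, in 12 of 22 cases with 0 higher (median -0.75).

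Genes of germ granules and of small RNA pathways rose by small amounts, while the oocyte, eggshell and maternal RNA list did not pass (1 of 31 higher and 0 lower, median 0.02, camera adjusted p = 0.209). Of 41 genes of germ granules and meiosis, 25 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.17. The meiotic cohesin gene rec-8 went from 157 ± 20.7 to 208 ± 4.72 CPM and syp-1, of the synaptonemal complex, from 69.2 ± 3.87 to 94.4 ± 2.04. Of 45 genes of small RNA pathways, 20 rose and 2 fell (21 and 2 adjusted over the list alone), with rrf-2, a polymerase gene of the same family as rrf-3, from 141 ± 7.22 to 220.1 ± 32.2 CPM, while the nuclear Argonaute gene nrde-3 fell from 85.0 ± 4.12 to 61.4 ± 8.12. With library totals 16 germ granule genes were higher. Without the 3 libraries that stand apart, which leaves 1 library at day 9, 9 germ granule genes and 9 small RNA pathway genes were higher and 3 of the latter lower. Small RNA pathway genes were higher in 12 cases without day 18 replicate 3. Camera gave adjusted p values of 7e-06 for DAF-16 targets, 5.15e-08 for moulting, 1.7e-14 for histones, 3.48e-05 for germ granules and 0.00153 for small RNA pathways. In the same order the alternative gave adjusted p = 0.175 with an estimated correlation, adjusted p = 0.113 with an estimated correlation, adjusted p = 0.0982 with an estimated correlation, adjusted p = 0.303 with an estimated correlation and adjusted p = 0.323 with an estimated correlation. By fold change, ugt-46 rose from 5.14 ± 0.381 to 36.0 ± 2.12 CPM (log2 2.81), and lys-2 (log2 -6.20) and thn-2 (55.7 ± 10.9 to 0.808 ± 0.375 CPM, log2 -6.15) fell. Another 4 rising and 3 falling genes have only a sequence name.

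A linear trend over the 6 ages was found in 4585 rising and 4943 falling genes. Lysosomal hydrolases fell by a median of 0.132 log2 units per day, with 39 of 47 lower and 2 higher (39 and 2 adjusted over the list alone, camera adjusted p = 3.14e-30, adjusted p = 0.0743 with an estimated correlation), and histones fell by 0.076 per day, with 27 of 34 lower and 4 higher (28 and 4 adjusted over the list alone, camera adjusted p = 1.07e-13, adjusted p = 0.103 with an estimated correlation). Cytosolic ribosomal protein genes rose in 75 of 80 cases and fell in 1, by a median of 0.025 per day (75 and 1 adjusted over the list alone, camera adjusted p = 7.14e-10, adjusted p = 0.358 with an estimated correlation). With library totals 59.4% of the genes with a trend rose, against 48.1%.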

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

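The alternative without the 3 libraries that stand apart was chosen after seeing the data, and all other alternatives before. No count of changed genes left the range of 1.5 times its main value with RLE scaling, DESeq2, protein-coding genes only or the replicate block. Among the genes named by rule for the comparisons, 304 tests under RLE scaling and 304 with no filter kept their direction and their side of the threshold, against 302 of 303 with DESeq2 and 293 of 304 with library totals. An adjusted p that DESeq2 gave as NA (583 genes for day 9 against day 6, 2618 for day 18 against day 15) was left out of its counts. Except where the number of genes tested explains it, the cause of the changes below was not tested.

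With a limit of 2-fold, which can only remove calls, the changed genes numbered 3127 (day 6 against day 3), 250 (day 9 against day 6), 371 (day 12 against day 9), 192 (day 15 against day 12), 386 (day 18 against day 15), 4525 (day 18 against day 3), 2062 (day 18 against day 9), 4249 (trend) and 5998 (6 ages). The stricter filter left 9344 genes to test and gave 4163 for day 6 against day 3, 5826 for day 18 against day 3, 6229 for the trend and 6825 for the 6 ages. With no filter the counts were 1964 for day 9 against day 6, 2204 for day 12 against day 9 and 1326 for day 15 against day 12. Library totals gave 862 for day 12 against day 9, 464 for day 15 against day 12 and 905 for day 18 against day 15. With only the 6 libraries compared, which leaves fewer samples to estimate the spread, 558 genes passed for day 9 against day 6, 508 for day 12 against day 9, 436 for day 15 against day 12 and 867 for day 18 against day 15. With as few libraries, 7223 passed for day 6 against day 3. The SD of deviations over genes was 0.165 to 0.269 at day 9, against 0.056 to 0.064 at day 6. The main model shares its estimate of spread over all ages, so its p-values for comparisons with day 9 may be too small. Without the 3 libraries that stand apart, only 1 library of day 9 is left (replicate 4, which correlates best with day 6) and the other ages supply the spread, so these counts do not show what the libraries left out contribute: 438 for day 9 against day 6, 287 for day 12 against day 9 and 3798 for day 18 against day 9.

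Leaving out each library in turn gave 10247 to 11463 genes for the 6 ages, 8959 to 9865 for the trend, 5852 to 6594 for day 6 against day 3, 477 to 960 for day 9 against day 6, 787 to 1271 for day 12 against day 9, 387 to 720 for day 15 against day 12, 784 to 1854 for day 18 against day 15, 7981 to 8696 for day 18 against day 3 and 5283 to 5847 for day 18 against day 9. The change of rrf-3 between day 18 and day 3, which passed no test, turned from 0.004 to -0.005 with protein-coding genes only, to -0.024 without day 3 replicate 1, to -0.003 without day 3 replicate 4 and to -0.005 without day 18 replicate 4. The highest value with 1 library left out was 0.028 (without day 3 replicate 3).

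Counts of gene lists rest on the assumed correlation. The preset value gave 22, 23, 27, 29 and 33 lists for the 5 steps, 26 for day 18 against day 3, 29 for day 18 against day 9 and 27 for the trend. For the steps 7, 10, 9, 12 and 13 of these were higher than other genes, and 15, 13, 18, 17 and 20 lower. It was 7 higher and 19 lower for day 18 against day 3, 12 and 17 against day 9, and 8 and 19 for the trend. Only part of the called lists is described above. With an estimated correlation 3, 0, 0, 0 and 2 passed for the steps, 2 for day 18 against day 3, 2 for day 18 against day 9 and 0 for the trend (unadjusted, 7, 4, 9 and 8 lists had p under 0.05 where 0 passed). The test fry, which asks only whether a list's genes move 1 way, gave 35 for day 6 against day 3, 15 for day 9 against day 6, 16 for day 12 against day 9, 19 for day 15 against day 12, 46 for day 18 against day 3 and 46 for the trend. The stricter filter gave 16 for day 12 against day 9. Leaving out 1 library gave 21 to 22, 13 to 23 (13 without day 9 replicate 4), 21 to 26, 25 to 30 and 32 to 35 lists for the steps, 25 to 27 for day 18 against day 3, 23 to 29 for day 18 against day 9 and 25 to 27 for the trend.

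The replicate numbers did not pair the libraries: of 45 pairs with the same number, 2 had deviations from the age means correlated above 0.1, the median correlation was -0.002, and 6 of 18 libraries correlated best with their own number. With the replicate number as a block, 7053, 967, 1304, 783 and 1759 genes passed for the 5 steps, 8813 for day 18 against day 3, 6229 for day 18 against day 9, 9422 for the trend and 10953 for the 6 ages. The block gave 21, 23, 24, 30 and 34 lists for the steps, 25 for day 18 against day 3, 30 for day 18 against day 9 and 27 for the trend. Of the genes named by rule, pqn-75 lost its call (adjusted p = 0.0547, day 9 against day 6), and no other call changed.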

Other observations

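Of the tests given here, those of a smaller share of body RNA, of a smaller share of intestine RNA and of a mislabelled age were chosen only after the result was seen. The bootstrap intervals given here resample genes as if they were independent. They do not resample libraries, so they do not measure the spread between samples and may be too narrow. Stress response genes showed no common rise with age. Of 16 cytosolic heat shock genes, 6 fell and 3 rose from day 3 to day 18 (camera adjusted p = 0.209). The small heat shock genes hsp-43 and hsp-17 fell from 162 ± 3.29 to 43.6 ± 6.42 CPM and from 77.6 ± 2.32 to 10.9 ± 1.64, and hsp-70 from 155 ± 21.8 to 40.9 ± 5.66 (SD, n = 3). In the list of the unfolded protein response of the endoplasmic reticulum, 7 of 18 genes fell and 2 rose (camera adjusted p = 0.743). The gene xbp-1, which encodes a transcription factor of this response, rose from 129 ± 10.8 to 267.6 ± 18.99 CPM, while the chaperone gene hsp-3 fell from 623 ± 27.8 to 461 ± 20.2. The mitochondrial chaperone gene hsp-6 rose from 623 ± 7.84 to 761.5 ± 9.14 CPM, in a list of 8 in which 3 fell and 1 rose (camera adjusted p = 0.941).

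The lists of other sperm genes and of male-enriched genes did not pass between day 18 and day 3, and passed as a trend over age. All 6 measured male-enriched genes rose from day 3 to day 18 (camera adjusted p = 0.055). The level of lov-1, a polycystin gene of male sensory neurons, went from 0.125 ± 0.0464 to 0.957 ± 0.307 CPM. As a trend over age the list passed (adjusted p = 0.0442), and the call ended with adjusted p = 0.291 with an estimated correlation, 0.0576 without day 3 replicate 4, 0.0529 without day 9 replicate 1, 0.0504 without day 9 replicate 3, 0.0527 without day 15 replicate 1 and 0.0915 without the 3 libraries that stand apart. Of 26 other sperm genes, 16 rose and 4 fell (camera adjusted p = 0.0722), with fer-1, needed for sperm membrane fusion, from 2.32 ± 0.26 to 13.8 ± 0.691 CPM. Their trend passed at adjusted p = 0.0376, and the call ended with adjusted p = 0.348 with an estimated correlation, 0.0519 without day 15 replicate 4 and 0.0692 with the stricter filter. Of 83 neuropeptide genes 33 rose and 11 fell (camera adjusted p = 0.0205, adjusted p = 0.679 with an estimated correlation). The level of flp-25 rose from 1.57 ± 0.417 to 14.7 ± 1.09 CPM and that of nlp-39 fell from 25.4 ± 2.21 to 4.14 ± 0.983. No explanation was tested for these values.

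The fall of the lysosomal hydrolases with age is the first pattern weighed. A smaller share of body RNA against germline RNA could be argued against as the whole cause only if it lowers all body tissues alike. That premise was not tested. Body lists did not move alike between day 18 and day 3, with medians of 0.545 for the neuronal genes, -1.085 for muscle and -1.683 for collagens. The lysosomal median minus that of 152 neuronal genes (ciliary, synaptic and neuropeptide lists, median log2 change 0.55 between day 18 and day 3) was -2.78 (95% bootstrap interval -4.08 to -2.05), and -1.22 (-1.57 to -0.89) between day 18 and day 9. The neuronal lists were picked after the results were seen, so this gap was known beforehand. As body lists did not move alike, it cannot decide the question. Other body lists fell too, and a share of body RNA as part of the fall stays open, of a size the tables do not give: the lysosomal median minus theirs was -1.15 (-2.56 to -0.27) for muscle, -1.13 (-2.56 to -0.22) for the basement membrane and -0.55 (-2.23 to 0.53) for collagens between day 18 and day 3, and -1.02 (-1.45 to -0.62), -0.80 (-1.39 to -0.37) and -0.56 (-1.02 to -0.19) between day 18 and day 9. For a smaller share of intestine RNA, 14 genes of intestinal structure and transport were the reference. The lysosomal median minus theirs was -1.39 (-1.82 to -0.85) between day 18 and day 9. This gap argues against such a share as the whole cause only if it lowers all intestinal genes alike, which was not tested. The vitellogenins, made in the intestine, did fall: their list level was -0.107, 1.032 and 0.102 in the day 9 libraries and -3.591, -2.775 and -3.791 in those of day 18. The gap therefore cannot decide the question. Between day 18 and day 3, at -1.28 (-2.67 to -0.26), this share and a change within intestinal cells cannot be told apart. There the interval reaches past the limit of -0.5 set for the test. Gene length is argued against (lysosomal median -2.26, -3.62 to -1.40, with a trend on length and level removed), and age, which the design names, stays open and was not tested on its own.

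The rise of moulting and ciliary genes between day 3 and day 6 is the second pattern. Gene length is argued against as the whole cause: the median of the 97 genes was 1.51, and 1.155 (0.632 to 1.305) after a trend on length and level was removed. Embryos held in or carried with the adults may be a source, although the growth protocol removes young larvae by sedimentation and egg clumps and worms with hatched young by Percoll: the median of 22 embryo markers fixed before this test was 0.77 (0.17 to 1.90), with 11 higher and 1 lower (camera p = 3.64e-06, p = 0.00349 with an estimated correlation), while of 29 early embryonic zygotic genes 3 rose and 9 fell (median -0.33). This source and a change in the adults cannot be told apart, since the interval reaches from below to above the limit of 0.5 set for the test, and the markers that rose include lpr-3 (6.14 to 45 CPM), hch-1 (15.8 to 55.8) and dex-1 (15.0 to 89.3), while lin-26 (118.7 to 124) and pes-1 (1.47 to 1.54) did not pass and tbx-9 (26 to 19.4) fell. At day 18 the marker median was -0.36 against day 3 (-0.66 to 0.22), with the ciliary median at 1.15, and age stays open, untested.

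The third pattern is the distance of day 9 replicates 1 and 3 and day 15 replicate 1 from their age. A mislabelled age is argued against: 0 of the 3 correlated best with an age beyond the next one, and 17 of the 18 libraries correlated best with their own age (day 9 replicate 4 did so with day 6). A trend on gene length took 16.3% of the variance of the deviations of day 9 replicate 1, between the bounds of 10% and 50% set for the test, so a partial effect of length remains open. It took 27.5% in day 9 replicate 3 and 13.8% in day 15 replicate 1. In the libraries that do not stand apart it took 0.9% (day 9 replicate 4) to 18.3% (day 12 replicate 4). Such shares are therefore not particular to the libraries apart, except for day 9 replicate 3. The share of nuclear rRNA in the library is open too: over the 18 libraries its correlation with the first component of the deviations, which held 44.0% of their variance, was -0.504 (Pearson's r, permutation p = 0.0593, Spearman's rho -0.282, permutation p = 0.258). Without the 2 libraries farthest from the median rRNA share it was 0.067 (permutation p = 0.797). Those are day 9 replicate 3 (23.95%) and day 15 replicate 1 (15.79%), 2 of the 3 libraries to be explained. That value therefore cannot argue against rRNA share for these 2. Day 9 replicate 1 lay at 22.5 on the component with 7.91% rRNA, near the median of 7.94%. Day 9 replicate 4, with 7.02%, lay at -7.7. A high rRNA share thus does not set day 9 replicate 1 apart. Deviations are taken from each age's mean, so the 18 permuted values are not independent. The correlation with rRNA share was the only relation of its kind computed, and no biological explanation was tested.

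A hypothesis on chromosomes was tested: that genes on the X chromosome shift as a group with age. Between day 18 and day 3 the median log2 change of 2036 X-linked genes lay below that of 11954 autosomal genes by a difference of -0.315 (95% bootstrap interval -0.373 to -0.268; camera p = 0.000683, adjusted over 7 comparisons 0.0012, and p = 0.0585 with an estimated correlation). Of the X-linked genes 948 fell and 483 rose, against 3425 and 3518 of the autosomal ones. Between day 18 and day 9 the difference was -0.38 (camera p = 3.86e-09, p = 0.00283 with an estimated correlation), and between day 6 and day 3 it was 0.122 (camera p = 0.393). Under the other settings the first difference ran from -0.442 (stricter filter) to -0.212 (no filter). The values may fit a shift of X-linked genes with age, as a hypothesis. Since germline-expressed genes are rare on the X chromosome, a larger share of germline RNA at day 18 would give the same sign. A smaller share would give the opposite sign, and neither was tested for this set.

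Other splits of the libraries gave fewer changed genes. For all 7 pairs of ages, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, with the highest other at 0, except 1 for day 15 against day 12, beside real counts of 7153, 1046, 1432, 851 and 1803 for the steps, 8926 for day 18 against day 3 and 6311 for day 18 against day 9; 10 splits are too few for a share under 0.05. The ages were also assigned to the libraries 100 times, the real assignment included. Only the real one gave as many as 11153 genes for the 6 ages (highest other 308). The same held for the trend, with 9528 genes (highest other 3). A random assignment of single libraries can thus be excluded as the source of these counts. Since the replicates of an age may be technical, chance differences between cultures cannot. Counts of gene lists with the preset correlation stood apart less, or not at all. The real split gave 22, 23, 27, 29 and 33 lists for the steps, and 26 and 29 for day 18 against day 3 and day 9. As many came from 8, 1, 1, 1 and 1 of 10 splits for the steps. For day 18 against day 3 it was 7 of 10, and for day 18 against day 9, 3 of 10. The highest others were 32, 21, 21, 28, 32, 36 and 31. The counts for day 6 against day 3 and day 18 against day 3 did not stand apart. The medians of their other splits were 23 and 26 lists. Chance cannot be excluded for these counts, nor for that of day 18 against day 9. Where only the real split gave as many, 10 splits are again too few for a share under 0.05. For the trend, 33 of the 100 assignments, the real one included, gave as many as 27 lists (highest other 37). Chance cannot be excluded for that number of lists.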
